A study of Mus musculus with 1115 samples.

How the data were processed

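Single cells of the cerebral cortex of C57BL/6 mouse embryos at embryonic day 13.5 were sorted after in utero electroporation of a plasmid with CAG-driven mRFP and Hes5 promoter-driven GFP, and were sequenced with a modified Smart-seq2 protocol, a full-length method without molecular identifiers. Each of the 1115 samples is a single cell, 731 in the Hes5_GFP group and 384 in the CAG_mRFP group; the authors' classes held 636 RGCs, 191 IPCs and 288 ENs. The deposited count table gives estimated counts for 16839 genes, eGFP and mRFP among them, as whole numbers. Back-calculation from the authors' normalized table, whose deposited values are the natural log of 1 plus counts per 10000 of each cell, showed that 2.88% of the nonzero entries had been fractional (tolerance 0.01) and were rounded. Mitochondrial content was deposited by the authors as a fraction of counts and is given as a percentage here. The submitters' processing notes name HISAT2, Seurat 2 and the mouse build mm10, without their order; the annotation, the counting tool and the way phases and cell classes were assigned are not given in the sources used here. The authors' cell table also gave dates of sorting and library preparation, a cell cycle phase, a cluster number and a cell class, and these annotations were used without a new clustering. A ribosomal RNA gene, AY036118, took 2.68% of all counts.

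No cell was removed. Each well held 1 sorted cell, so no doublet caller was run. Total counts per cell ranged from 2207 to 1982807 in Hes5_GFP and from 814 to 1952854 in CAG_mRFP, and the highest mitochondrial percentage was 4.92%. The median mitochondrial percentage was 1.35% in Hes5_GFP and 1.56% in CAG_mRFP.

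The comparisons, gene lists, naming rule and alternatives were fixed before the data were examined, except where stated. The design called for a test across independent units if the cell table held any, and otherwise for summed values with counting intervals. The table names no animal, but it gives 5 sort days, and embryos of one stage that were sorted on different days are different embryos, so the sort day was taken as the unit. This choice was made after the cell table had been seen, and the days hold whatever differed between sessions as well as between embryos. The 4 days with at least 10 cells of each group were tested, and 3 cells of the remaining day entered pooled values only. RGCs were tested over 3 days, and IPCs and ENs over 2, under the same minimum. The values of the original plan, summed CPM with 95% exact Poisson intervals and log2 ratios within the 5 plate batches that held both groups, are given beside the tests for Sox9, and within-batch log2 ratios are given for Hes5. Groups sorted on the same day were treated as pairs because they shared that day; the correlations of their profiles after centering were 0.148, 0.199, 0.275 and 0.389, and the day 3 Hes5_GFP profile correlated more with the day 4 CAG_mRFP profile (0.310) than with its own.

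Counts were summed per day and group and tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with the sort day as a block and total counts as library size, for genes with at least 5 summed CPM in either group. Adjusted p-values are Benjamini-Hochberg values, called at 0.05, and were also computed over single lists. Differences between classes in the group effect were tested as interaction terms in the same way. G1 was compared with G2M within Hes5_GFP RGCs by the same test over 3 days, with a lower minimum of 5 cells of each phase per day. The tests were run on simulated data with 200 changed genes, together with DESeq2 1.42.0. Shares of cells have 95% exact Clopper-Pearson intervals and were compared between groups, over the days with at least 10 cells of each group in the class, with an exact two-sided sign-flip test.

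Genes were named by a rule. Those with at least 20 summed CPM in either group, a read in at least 10% of the cells of either group and one sign in every plate batch with at least 10 cells of each group were ranked by the mean within-batch log2 ratio with a prior of 1 CPM, and the 12 highest and 12 lowest were named, without mitochondrial, ribosomal protein, and numbered Gm or Rik genes. A further 8 genes were always given. The genes past the test were also named, a choice made after their values had been seen. For correlations with Sox9, log2(CPM + 1) values of genes with at least 20 mean CPM were compared across RGCs within strata of at least 20 cells of one batch and group, and the 10 highest and 10 lowest with one sign in all strata were named. The lists covered radial glia, intermediate progenitors, cortical neurons, Cajal-Retzius cells, endothelium, pericytes, microglia, erythroid cells, meningeal fibroblasts, cortical hem and choroid plexus, Notch receptors and targets, Notch ligands and proneural genes, BMP and Id, Sox, FGF and ERK, Wnt, Shh, S phase, G2/M phase, G1 regulators and cell cycle inhibitors, glial lineage, matrix and adhesion, deep and upper layers, glycolysis, immediate early, heat shock and stress, and mitochondrially encoded genes. A further list and some members of others are not reported here. Medians of list log2 ratios were taken from counts pooled over all cells of each group, without the day block. The numbers of members with a higher or lower value were counted in the same ratios. Values of single genes given with an SE are fitted. Each list median was set against 10000 random lists of equal size drawn from 20 bins of mean CPM. Examples were taken in the order of mean CPM, together with members past a test.

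Other settings were per-cell mean CPM and the normalized values (both with limma 3.58.1), TMM scaling, within-batch means, other CPM minimums, a filter of at least 2000 genes and under 10% mitochondrial counts (140 cells had fewer genes), thinning of each cell to 44732 counts, the 10th percentile, leaving out each plate batch, and Leiden clustering at resolutions 0.6 and 1.5 (scanpy 1.11.5, 2000 variable genes, 20 principal components, 15 neighbours). Thinning kept 682 Hes5_GFP and 321 CAG_mRFP cells. Leaving out each day, omitting the day block, taking the plate batch as the unit and block, DESeq2, and leaving out cluster 7 or a shallow plate were added after seeing the data, as were correlations without the CAG_mRFP stratum or in the cells kept by thinning, all settings for the counts of genes and other CPM minimums for single genes. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Gene positions are from GENCODE M21 on mm10, counted from 1.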

Results

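Single cells of the mouse cerebral cortex at embryonic day 13.5 were profiled after in utero electroporation of a reporter plasmid, in which the ubiquitous CAG promoter drove the red protein mRFP and a Hes5 promoter, a readout of Notch signalling, drove the green protein GFP. Cells positive for both reporters made up the Hes5_GFP group (65.6% of 1115 cells), and cells with mRFP alone made up the CAG_mRFP group (34.4%). The authors' annotation called 57.04% of the cells radial glial cells (RGCs), 17.1% intermediate progenitor cells (IPCs) and 25.8% excitatory neurons (ENs). The cells had been sorted on 4 days that held at least 10 cells of each group, called days 1 to 4 here, and on a further day with 3 cells, which entered pooled values only. The sort day served as the replicate, because embryos of one stage sorted on different days were different embryos. The deposited table names no animals, so this was an inference, and how many embryos each day pooled was not given in the sources used here.

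The median total was 269305 counts per cell in Hes5_GFP (range 2207 to 1982807, median 3535 detected genes) and 245651 in CAG_mRFP (range 814 to 1952854, median 2743 detected genes). By day, the Hes5_GFP medians were 948677, 198148, 221129 and 325441 counts and the CAG_mRFP medians were 741666, 916847, 133152 and 290257. Plate and group were largely confounded on days 3 and 4, when each plate held a single group. A plate of 80 CAG_mRFP cells sorted on day 3 had a median of only 30740 counts. On day 2, 26 of 55 Hes5_GFP cells shared a plate with the 23 CAG_mRFP cells. The others were on another plate and were prepared on another date. All CAG_mRFP cells of plate batch L2 were sorted on day 4 and those of batch L3 on day 3. The Hes5_GFP cells of these batches came from other days as well. Ratios within these batches therefore also compare sort days. No pair of cells had identical values. The libraries carried no molecular identifiers, so the Poisson intervals below cover the counting of reads and not of molecules. They also leave out the spread between cells. Neither they nor the binomial intervals of cell shares cover the spread between days.

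The first comparison asked how Sox9 and the rest of the transcriptome differed between the sorted groups, over all cells. Averaged over days, RGCs made up 77.8% of Hes5_GFP and 24.1% of CAG_mRFP, and ENs made up 4.22% and 54.7%. Values over all cells therefore mix class composition with levels within a class. Sox9, which encodes an SRY-box transcription factor of neural stem cells, was detected at 583.5 ± 193.6 CPM (SD, n = 4 days) in Hes5_GFP and at 167.1 ± 130 CPM in CAG_mRFP, a fitted log2 ratio of 2.10 ± 0.31 (SE). Hes5, the endogenous counterpart of the reporter's promoter and a Notch effector, reached 54.9 ± 17.5 against 13.9 ± 9.49 CPM (log2 ratio 2.22 ± 0.52). Tubb3, which encodes a neuronal tubulin, went the other way, at 264.8 ± 78.8 CPM in Hes5_GFP and 1301 ± 225.5 CPM in CAG_mRFP. Each of these differences had the same direction on 4 of 4 days.

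Over all 10517 genes tested, Tubb3 passed in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (log2 ratio -2.33 ± 0.14, adjusted p = 0.00792), whereas Sox9 (adjusted p = 0.0666) and Hes5 (adjusted p = 0.156) did not. Sox9 did pass in several other settings, such as without day 1, and its adjusted p ranged from 3.16e-09 to 0.423 over the settings (Benjamini-Hochberg adjustment in edgeR, limma or DESeq2). Of the 8 genes that were always to be given, 5 passed in edgeR with Benjamini-Hochberg values adjusted over the list alone: Sox9 (adjusted p = 0.00155), Hes5 (0.00922), Hes1, another Notch effector (log2 ratio 3.39 ± 0.94, adjusted p = 0.0164), Pax6, a regulator of dorsal cortical progenitors (1.62 ± 0.37, adjusted p = 0.00922), and Tubb3 (1.81e-05). The other members were Mki67, a proliferation marker (0.84 ± 0.39), Neurog2, a proneural factor (0.65 ± 0.47), and Eomes, the marker of intermediate progenitors (-0.14 ± 0.67), none of which passed. When single days or batches were left out, Hes1 ran from 2.54 to 4.86, Mki67 from 0.59 to 1.28, Neurog2 from 0.20 to 1.05 and Eomes from -0.86 to 0.27. Summed over all cells, Sox9 stood at 494.8 CPM in Hes5_GFP (95% exact Poisson interval 492.1 to 497.5) and 127.9 CPM in CAG_mRFP (125.96 to 129.9). Within the 5 plate batches that held both groups, the log2 ratio of Sox9 averaged 2.17 (range 1.25 to 3.17) and that of Hes5 averaged 2.27 (range 1.41 to 3.18). Sox9 lies on chromosome 11, from 112782224 to 112787760 on the plus strand of the mm10 build, with 3 exons, and Hes5 lies on chromosome 4, from 154960923 to 154962371 on the plus strand, also with 3 exons.

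**Figure D1:**
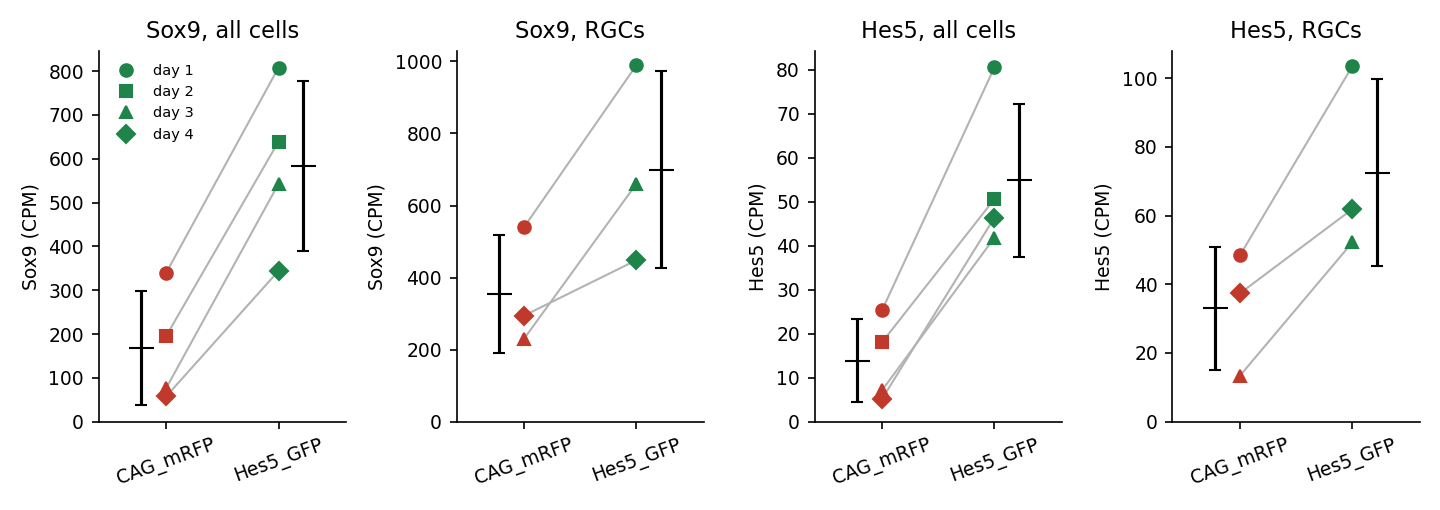
Sox9 and Hes5 in CPM (linear y axes) for each sort day and group, over all cells and over RGCs; each symbol is the summed count of one day and group, gray lines join the groups of a day, and black bars give the mean ± SD over days. Sox9 was higher in Hes5_GFP on every day shown, by a fitted log2 ratio of 2.10 over all cells and 1.003 over RGCs.

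In all, 42 genes differed between the groups, 6 higher and 36 lower in Hes5_GFP, a balance of directions that several other settings did not share. The 6 that rose had log2 ratios between 1.34 and 2.62: Schip1, which encodes a cytoskeletal adaptor protein (2.62 ± 0.25, SE), Slc1a3, the glutamate transporter GLAST of radial glia (2.58 ± 0.29), Nup62, a nuclear pore component (1.77 ± 0.23), Mpped2 (1.64 ± 0.20), Mcm5, a subunit of the replicative helicase (1.47 ± 0.16), and Slbp, which binds histone mRNA (1.34 ± 0.15). Slc1a3 stood at 424.4 ± 129.8 CPM in Hes5_GFP and 74.4 ± 33.99 CPM in CAG_mRFP (SD, n = 4 days). Among the 36 that fell (log2 ratios -3.83 to -1.23) were the transcription factor genes Neurod6 (-2.63 ± 0.17), Neurod1 (-2.95 ± 0.33), Bcl11b (-2.73 ± 0.34) and Bcl11a (-1.56 ± 0.18). The genes named here were ordered by their known function after their values had been seen, and no such grouping was tested for enrichment. Those that encode proteins of microtubules, actin or their regulation were Dpysl3 (-2.78 ± 0.15), Crmp1 (-2.17 ± 0.21), Dcx (-2.66 ± 0.30), Map2 (-1.997 ± 0.16), the kinesin gene Kif21b (-3.12 ± 0.23), Dbn1 (-1.37 ± 0.13) and the tubulin gene Tuba1a (-1.23 ± 0.15). Those of the cell surface were Robo2, a Slit receptor (-3.06 ± 0.28), L1cam, an adhesion molecule (-3.31 ± 0.40), Plxna2, a semaphorin coreceptor (-2.03 ± 0.26), the glypican gene Gpc2 (-2.58 ± 0.28) and Cd24a (-1.78 ± 0.23). Further genes that fell were Dusp4, which encodes a MAP kinase phosphatase (-3.83 ± 0.34), Tiam2, an activator of Rac (-3.59 ± 0.30), the somatostatin receptor gene Sstr2 (-2.23 ± 0.24), Rtn1 (-2.17 ± 0.24), Mllt11 (-2.62 ± 0.15), Nrep (-2.55 ± 0.22) and Nnat (-1.51 ± 0.15). Neurod6 stood at 451.8 ± 244.5 CPM in Hes5_GFP and 2743 ± 1264 CPM in CAG_mRFP (SD, n = 4 days). All 42 had one direction on 4 of 4 days, and their adjusted p lay between 0.00792 and 0.0475 in edgeR with Benjamini-Hochberg adjustment.

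The replication behind the p-values is how the difference between the groups varied over the sort days, because the day block removes the level of each day. To estimate this variation for a gene, edgeR also drew on the other genes tested. The count was 0 in edgeR without day 2, without day 3 or without day 4 (1247, 821 and 769 genes at an unadjusted p under 0.05). Without day 1 it went from 0.399% to 2.43% of the tested genes, while 18 passed without the day as a block and 2.46% passed with the plate batch as the unit, although batches L1, L2 and L3 shared days 3 and 4. Of the genes called, 14.3% were higher in Hes5_GFP in the test over 4 days, against 53.3% without day 1, 45.6% by plate batch, 49.1% with DESeq2 and 49.4% in per-cell mean CPM. DESeq2 called 1163, but on simulated data of this size it also called 1.23% to 1.63% of the unchanged genes, against 0 to 8 such genes for edgeR, which in turn recovered 0% of genes changed 2-fold, 19.5% of those changed 4-fold and 52.5% of those changed 8-fold.

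The largest differences by the naming rule, which ranked genes by the mean of their within-batch log2 ratios, did not pass the test. The 12 highest averaged 3.28 to 5.32 within batches and were led by the reporter transcript eGFP (247.004 CPM in Hes5_GFP, 7.36 CPM in CAG_mRFP, fitted log2 ratio 5.44 ± 1.01). The others were Ppargc1a, a coactivator of mitochondrial genes (6.20 ± 2.45), Dapp1 (4.27 ± 1.48), Plce1, a phospholipase C (3.87 ± 0.68), Stac (4.57 ± 1.57), Sft2d2 (6.10 ± 2.51), Hes1, Eepd1 (4.26 ± 1.51), Rbm20, a splicing regulator (4.80 ± 1.66), the homeobox gene Prrx1 (4.15 ± 1.66), Rgcc (3.43 ± 1.39) and the endothelin receptor gene Ednrb (3.43 ± 1.44). Their adjusted p ranged from 0.0983 to 0.371 in edgeR with Benjamini-Hochberg adjustment. The 12 lowest averaged -4.82 to -4.16 within batches: Ndst3, Pdzrn3, the neuronal transcription factor gene Myt1l, Ttc39b, Csrnp3, Chga, a component of secretory granules, the axonal adhesion gene Cntn2, Ccser1, the cannabinoid receptor gene Cnr1, the splicing regulator Rbfox1, the guidance gene Sema3c and Atcay. Their fitted log2 ratios lay between -6.72 and -5.08, with adjusted p from 0.124 to 0.297 in edgeR with Benjamini-Hochberg adjustment. Ndst3, for example, stood at 2.43 CPM in Hes5_GFP and 94.9 CPM in CAG_mRFP.

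Over all cells, radial glia markers lay higher and cortical neuron markers lower in Hes5_GFP, in groups that differed in their cell classes. List medians are from counts pooled over the cells of each group and not from the fits. All 15 radial glia markers had a higher pooled value in Hes5_GFP (median log2 ratio 2.05, above every one of 10000 random lists of matched expression). 1 passed over all genes (Slc1a3) and 9 adjusted over the list alone, including Ddah1 (2.28 ± 0.53) and Fabp7, a brain lipid-binding protein (2.44 ± 0.84); Vim, an intermediate filament gene, was not among them (0.71 ± 0.30). All 15 cortical neuron markers had a lower value (median -2.36, below every random list). 5 fell over all genes (Neurod6, Tubb3, Dcx, Neurod1 and Bcl11b) and 12 adjusted over the list alone. The 10 intermediate progenitor markers had a median of -0.51 (percentile 1.12), and Sstr2 alone fell by either adjustment, while Gadd45g (-0.01 ± 0.30) and Mfng (-0.53 ± 0.45) did not pass. The 7 deep layer genes had a median of -1.42 (percentile 0.02), with Bcl11b lower over all genes and 4 lower adjusted over the list alone (Sox5, Bcl11b, Foxp2 and Tbr1). The 6 upper layer genes had a median of -0.74 (percentile 1.11); none passed over all genes, and among those past the test adjusted over the list alone Cux1 was higher (0.60 ± 0.19) and Cux2 was lower (-2.03 ± 0.40). The upper layer median was positive with the authors' normalized values.

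Over all cells, cell cycle genes were higher in Hes5_GFP. Within RGCs alone the pooled medians were 0.09 for S phase and 0.70 for G2/M genes. All 42 S phase genes had a higher value (median 1.09, percentile 100); Mcm5 and Slbp rose over all genes and 27 did adjusted over the list alone, among them Rrm2 (0.96 ± 0.14) and Rrm1 (1.01 ± 0.16), subunits of ribonucleotide reductase. All 51 G2/M genes also had a higher value (median 1.42, percentile 100), but none passed over all genes and 7 did adjusted over the list alone (Tmpo, Ckap2, Kif20b, Hjurp, Kif2c, Lbr and Ckap5); the abundant Hmgb2 (0.94 ± 0.34) and Top2a (1.05 ± 0.44) did not. Of 16 G1 regulators (median 0.69, percentile 99.95) none passed over all genes and 2 did adjusted over the list alone, Ccnd2 (0.77 ± 0.15) and Cdk6 (1.16 ± 0.18), which act in the G1 phase, while Cdk4 was at -0.03 ± 0.12.

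Among signalling lists no gene passed over all genes. The 8 Notch receptors and targets had a median of 1.91 (percentile 100), with Hes1 and Hes5 higher adjusted over the list alone, and Notch1 (1.54 ± 0.54) and Hey1 (0.06 ± 0.22) not passing. The groups were sorted by a Hes5 promoter reporter, and Hes5 is in this list. The high median of the list is therefore not independent of the sort. The 7 Notch ligands and proneural genes had a median of -0.18 (percentile 22.7), a sign that turned within batches and with the authors' normalized values, and Dll3 alone was lower adjusted over the list alone (-2.09 ± 0.39). Adjusted over the list alone, 2 of 9 FGF and ERK genes were higher (Fgfr3 and Fgfr1; median 1.09, percentile 99.6), 2 of 10 Wnt genes were higher (Tcf7l2 and Wnt7a) and 2 lower (Wnt7b and Nkd1; median 1.38, percentile 100), and 2 of 7 Shh genes were higher (Gas1 and Boc; median 0.91, percentile 99.4). Of 6 BMP and Id genes (median 1.09, percentile 99.6) Id4 was higher and Id2 lower, and of 10 Sox genes (median 1.08, percentile 99.95) Sox9 was higher and Sox11 (-1.86 ± 0.28) and Sox5 (-1.41 ± 0.23), genes of postmitotic neurons, were lower, each adjusted over the list alone.

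Of 15 glycolysis genes none passed over all genes and 9 were higher adjusted over the list alone (median 0.64, percentile 99.8), including Pkm (0.37 ± 0.10), Eno1 (0.75 ± 0.12) and Ldha (1.24 ± 0.24). Of 8 glial lineage genes (median 0.12, percentile 53.5) Slc1a3 rose over all genes, and adjusted over the list alone 3 were higher (Fabp7, Slc1a3 and Fgfr3) and Nfib was lower (-1.19 ± 0.19). The 12 matrix and adhesion genes (median 0.31, percentile 86.3) had only Ncan lower adjusted over the list alone (-0.85 ± 0.16), and the 7 immediate early genes (median 0.22, percentile 68.6, negative when plate batch L2 was left out) had only Jun higher (1.70 ± 0.42). None of the 12 heat shock and stress genes (median 0.17, percentile 68.1, negative in per-cell mean CPM) and none of the 13 mitochondrially encoded genes (median -0.23, percentile 3.89) passed by either adjustment. Over the measured genes of all lists together, 9 passed over all genes and 80 adjusted over the lists together. Markers of other cell types were scarce: of the 2 measured Cajal-Retzius genes Nhlh2 was lower adjusted over the list alone (-5.02 ± 1.28). The single measured genes of the endothelial (Cldn5, pooled log2 ratio 2.63) and erythroid (Hbb-bs, pooled -2.56) lists did not pass, and the latter value changed sign within batches. No pericyte, microglia, meningeal fibroblast, or cortical hem and choroid plexus marker reached 5 CPM.

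**Figure D2:**
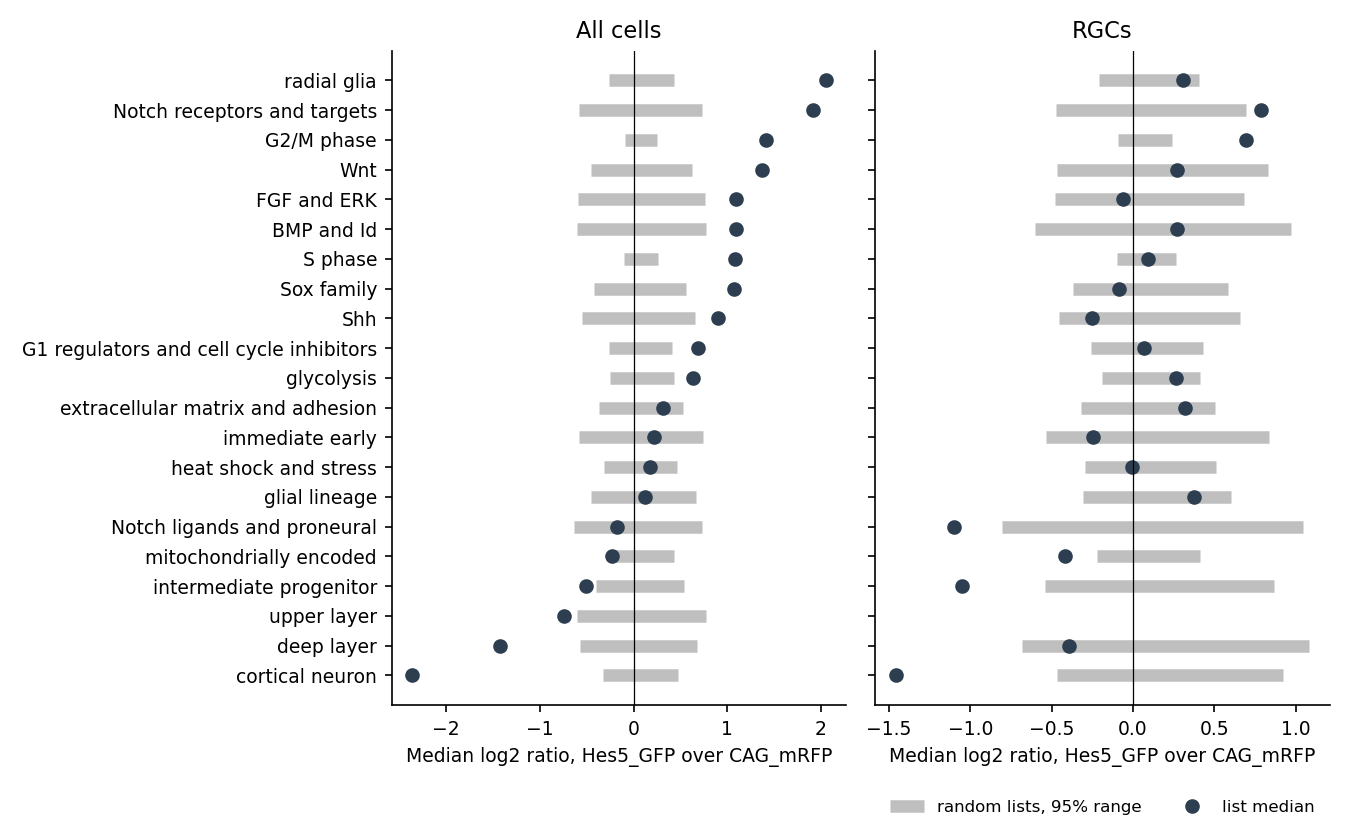
Median log2 ratio of Hes5_GFP over CAG_mRFP in counts pooled over cells, for each gene list with at least 5 measured members (x axes), over all cells and over RGCs. Gray bars give the 95% range of 10000 random lists matched on expression. Radial glia (2.05) and cortical neuron (-2.36) markers lay farthest from 0 over all cells, while over RGCs the G2/M genes (0.70) and the Notch receptors and targets (0.79) lay above their ranges, and cortical neuron (-1.46), intermediate progenitor (-1.05), Notch ligand and proneural (-1.10) and mitochondrially encoded genes (-0.42) lay below theirs.

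The groups also differed in their cell classes. RGCs made up 77.2% of Hes5_GFP (95% exact binomial interval 73.9% to 80.2%) and 18.8% of CAG_mRFP (72 cells, 14.97% to 23.02%), and ENs made up 6.16% and 63.3%. Averaged over days, RGCs were 77.8 ± 3.48% against 24.1 ± 21.3% (SD, n = 4 days), ENs were 4.22 ± 3.15% against 54.7 ± 25.9%, and IPCs were 17.99 ± 3.48% against 21.2 ± 5.87%. The RGC share was higher and the EN share lower in Hes5_GFP on 4 of 4 days, and each two-sided exact sign-flip test gave p = 0.125, the smallest value 4 days allow. On day 1, 54.2% of CAG_mRFP cells were RGCs.

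**Figure D3:**
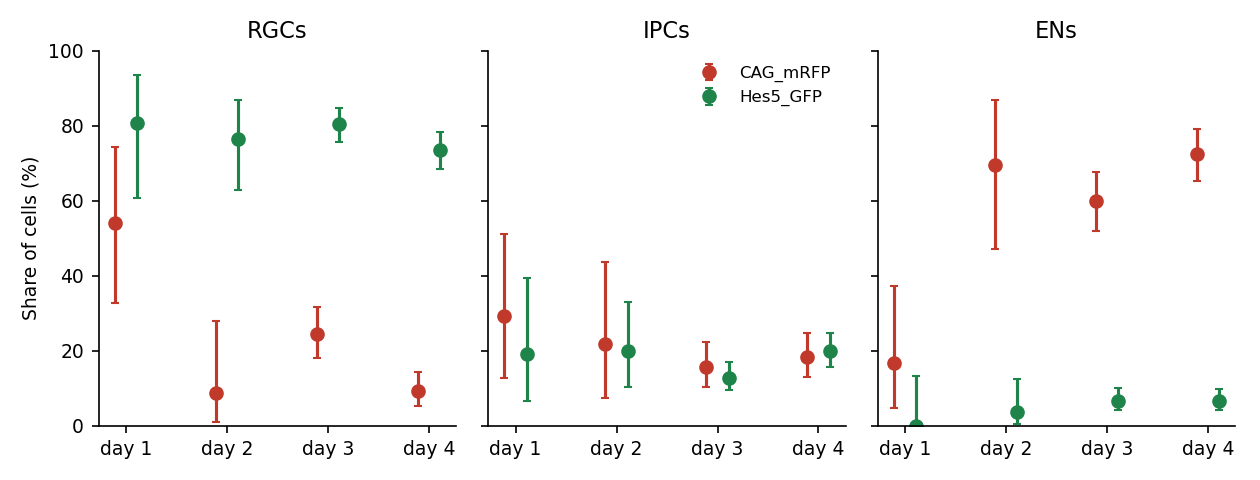
Share of cells (%, y axes) annotated as RGCs, IPCs and ENs on each sort day, in CAG_mRFP (red) and Hes5_GFP (green); points are shares and bars are 95% exact binomial intervals. RGCs were the most frequent class of Hes5_GFP on every day, and ENs were that of CAG_mRFP on days 2, 3 and 4.

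The second comparison asked whether Sox9 differed between the groups within RGCs, apart from their cell classes. It was fitted over days 1, 3 and 4, because day 2 held only 2 CAG_mRFP RGCs. Sox9 was at 699.5 ± 272.7 CPM in Hes5_GFP RGCs and 354.8 ± 163.5 CPM in CAG_mRFP RGCs (SD, n = 3 days), a fitted log2 ratio of 1.003 ± 0.28 with the same direction on 3 of 3 days. The test did not pass over all genes (adjusted p = 0.999) or adjusted over the list alone (adjusted p = 0.0855, edgeR with Benjamini-Hochberg adjustment). Summed over cells, Sox9 stood at 644.4 CPM (640.8 to 648.05) against 431.04 CPM (422.2 to 440.01). Within the 4 plate batches with enough RGCs, its log2 ratio averaged 0.85 and ranged from -0.03 in batch L1 to 1.64 in batch L2. In batch L2 all CAG_mRFP cells had been sorted on day 4, but Hes5_GFP cells also on days 2 and 3. Within single sort days and preparation dates with enough RGCs, the log2 ratio of Sox9 was 0.87 (day 1), 2.11 and 0.81 (day 3) and 1.05 (day 4). Hes5 stood at 72.5 ± 27.2 against 33.04 ± 17.9 CPM (log2 ratio 1.26 ± 0.69), Hes1 at 1.53 ± 0.87, Pax6 at 0.37 ± 0.30 and Mki67 at 0.50 ± 0.37, and none of these passed. The median fitted log2 ratio of all 10405 genes tested in RGCs was 0.39 (0.31 with TMM scaling), so Pax6 and Mki67 lay near this background. The fitted value of 1.003 for Sox9 lay above this background but is not corrected for it. Eomes (-0.82 ± 3.06), Neurog2 (-0.15 ± 1.29) and Tubb3 (0.27 ± 1.06) did not pass and changed sign between settings. Mki67 was at -0.031 without batch L2, Pax6 ran from 0.094 to 0.71 and Hes1 from 0.79 to 2.32 when single days or batches were left out, and the log2 ratio of Hes1 was -0.077 on day 4.

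The groups differed in how the class was spread over clusters. In Hes5_GFP the authors' clusters 0, 1 and 3 held 38.5%, 30.9% and 20.6% of the RGCs and cluster 7 held 9.22%. In CAG_mRFP clusters 0, 1 and 3 held 9, 23 and 6 of the 72, cluster 7, whose cells had a median of 1168 detected genes, held 19, and cluster 2, otherwise a neuron cluster, held 13 with Sox9 at 5.39 CPM. Sox9 in CAG_mRFP was at 638.6, 423.3 and 597.3 CPM in clusters 0, 1 and 3 and at 166.5 CPM in cluster 7, against 687.5, 637.6, 598.9 and 572.7 CPM in Hes5_GFP. Over clusters 0, 1 and 3 alone, the log2 ratio of Sox9 averaged 0.71 over the days (SE 0.06, range 0.62 to 0.83, higher in Hes5_GFP on 3 of 3 days), with 38 cells in CAG_mRFP. In counts summed over these cells it was 0.35, against 0.58 for the whole class, and within cluster 1 it averaged 0.37 over 2 days.

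No gene passed among the 10405 tested in RGCs with edgeR's test and Benjamini-Hochberg adjustment, and 2.05% had an unadjusted p under 0.05. DESeq2 called 1.21% (92.1% of these higher, 10 genes lower), against the 2.09% to 2.24% of unchanged genes that it called on simulated data of this size. In those data edgeR recovered 0%, 9% and 32% of genes changed 2-fold, 4-fold and 8-fold, with 0 to 3 false calls.

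The 12 genes with the highest within-batch values (4.05 to 6.58) were led by both reporters. The transcript eGFP stood at 315.4 against 1.999 CPM (log2 ratio 8.08 ± 1.20), and mRFP, although the sort required it in both groups, at 4999 against 151.8 CPM (5.13 ± 2.63). The log2 ratio of mRFP was 13.08 within batch 01 and 2.51, 3.82 and 0.56 within batches L1, L2 and L3, and its fitted value was 2.66 without day 1 and 9.09 without day 3. The others were Eaf1, an elongation factor partner (32.2 and 0.761 CPM), Wdpcp, a ciliary gene with no counts in CAG_mRFP RGCs (26.6 and 0 CPM), Rassf4, Tbcd, a tubulin-folding cofactor (71.2 and 9.85 CPM), Tmem18, Cds2, the ciliary gene Dzip1l, Prmt6, an arginine methyltransferase, Hmgxb4 and the homeobox gene Pknox2. The 12 lowest (-2.71 to -1.53) were Idnk, Tmem14a, Plekha8, Zfp532 (25.1 and 96.8 CPM), Tmeff1, Cdyl2, Prune2, Ak4, the histone demethylase gene Kdm5c (32.98 and 90.2 CPM), Snhg3, Hist3h2ba and Rbm45. None of these 24 passed, with an adjusted p of 0.999 for each in edgeR with Benjamini-Hochberg adjustment, and 7 of them were named again after cells with few genes were left out.

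In RGCs no member of any list passed over all genes or adjusted over the list alone. The G2/M list had the most one-sided values: 49 of 51 genes were higher in Hes5_GFP (median 0.70, percentile 100), such as Top2a (0.66 ± 0.35), although Hmgb2 was at -0.11 ± 0.32. By the authors' phase calls, which were not recomputed at equal depth, 54.4% of Hes5_GFP RGCs and 27.8% of CAG_mRFP RGCs were in G2M, and 32.3% and 68.1% were in G1. On day 1 the G2M shares were 14.3% and 53.8%, and over days they averaged 41.8 ± 24.1% and 32.6 ± 20.5% (SD, n = 3 days; two-sided exact sign-flip p = 1). The Notch receptors and targets, a list not independent of the sort by a Hes5 promoter reporter, had a median of 0.79 (percentile 98.8). Notch1 was at 0.60 ± 0.42 and Notch2 at -0.25 ± 0.39. Radial glia markers had a median of 0.31 (percentile 90.05), with Ddah1 at 0.01 ± 0.34 and Slc1a3 at 0.79 ± 0.25. Lists of the later lineage lay lower in pooled counts. The 13 cortical neuron markers had a median of -1.46 (percentile 0), with Neurod6 at 11.2 and 412.01 CPM. The 8 intermediate progenitor markers had a median of -1.05 (percentile 0.13). The 5 Notch ligands and proneural genes had a median of -1.10 (percentile 0.725) that turned positive within batches. Lower in every plate batch were 1 of the 13, 0 of the 8 and 0 of the 5. Tubb3 was at -1.13 in pooled counts although its fitted value was positive, and Neurog2 was at -2.48, far below its fitted value. In CAG_mRFP RGCs Neurod6 stood at 22.1 CPM in the 38 cells of clusters 0, 1 and 3, at 5985 CPM in the 13 cells of cluster 2 and at 997.9 CPM in the 19 cells of cluster 7, against 6.07 CPM in clusters 0, 1 and 3 of Hes5_GFP. Tubb3 went the other way in clusters 0, 1 and 3, at 40.4 CPM in CAG_mRFP and 58.9 CPM in Hes5_GFP. In CAG_mRFP RGCs it stood at 1448 CPM in cluster 2 and 289.9 CPM in cluster 7. Over all CAG_mRFP RGCs Tubb3 ranged from 9.996 to 460.95 CPM over days. The 13 mitochondrially encoded genes had a median of -0.42 (percentile 0.1).

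The remaining RGC lists lay inside the range of random lists, except the erythroid list. Their medians were 0.09 for S phase and 0.07 for G1 regulators, both of which turned negative with TMM scaling, 0.26 for glycolysis, 0.38 for the glial lineage, 0.32 for matrix and adhesion, 0.27 for Wnt, and 0.27 for BMP and Id. They were -0.08 for the Sox family, -0.06 for FGF and ERK, -0.25 for Shh, -0.40 for deep layer, -0.25 for immediate early and -0.01 for heat shock and stress genes, each of which turned positive within batches, and 0.18 for upper layer genes, which turned negative without day 1. The 3 measured erythroid genes had a median of -2.55, which was below the random range and turned positive within batches. The single endothelial gene, Cldn5 (pooled log2 ratio 2.98), and meningeal gene, Col1a2 (pooled 2.43), did not pass. No Cajal-Retzius, pericyte, microglia, or cortical hem and choroid plexus marker reached 5 CPM. TMM scaling shifted log2 ratios by -0.11 in RGCs and by -0.07 over all cells.

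The detection of mRFP differed between classes of the same sort. In CAG_mRFP, 43.1% of RGCs (31 of 72, 95% exact binomial interval 31.4% to 55.3%) had an mRFP read, against 78.3% of IPCs (66.7% to 87.3%) and 85.2% of ENs (80.1% to 89.4%), and in Hes5_GFP the share was 63.1% of RGCs (58.99% to 67.1%). The median totals were 200024 counts in CAG_mRFP RGCs and 240175 in CAG_mRFP ENs. Over days, RGCs with an mRFP read were 73.8 ± 23.2% in Hes5_GFP and 44.8 ± 16.2% in CAG_mRFP (SD, n = 3 days; two-sided exact sign-flip p = 0.25, the smallest possible).

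**Figure D4:**
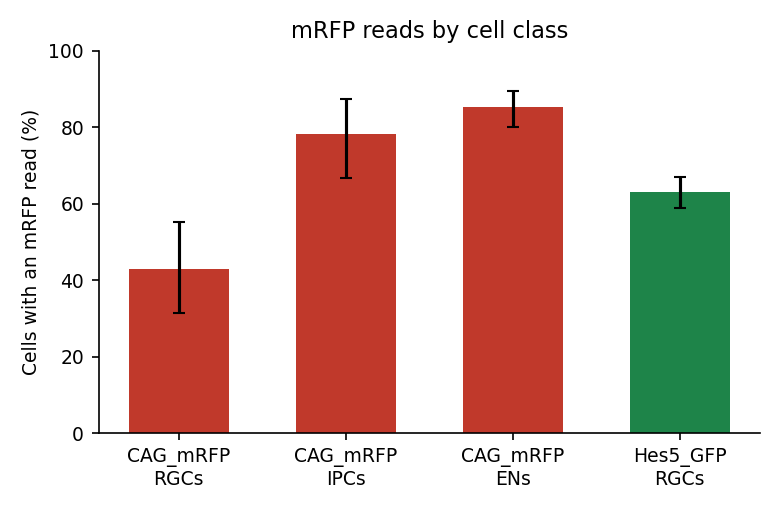
Share of cells (%, y axis) with at least 1 mRFP read, for the classes of CAG_mRFP and for the RGCs of Hes5_GFP; bars are shares over all cells and error bars are 95% exact binomial intervals. RGCs of CAG_mRFP had the lowest share, 43.1%, and ENs of the same group the highest, 85.2%.

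The third comparison set Sox9 across cell classes. Whether Sox9 was used to define the authors' classes is not given in the sources used here. Differences in Sox9 between classes may therefore follow in part from their definition. In Hes5_GFP it stood at 644.4 CPM in RGCs, 88.1 CPM in IPCs and 48.1 CPM in ENs, and in CAG_mRFP at 431.04, 91.1 and 57.4 CPM. At least 1 Sox9 read was found in 95.4% of Hes5_GFP RGCs and 62.5% of CAG_mRFP RGCs, in 54.9% and 56.5% of IPCs, and in 42.2% and 22.2% of ENs. The RGC share in clusters 0, 1 and 3 was 99.1%, 98.9% and 98.3% in Hes5_GFP and 100%, 91.3% and 100% in CAG_mRFP. In cluster 7 it was 65.4% and 42.1%, and in the CAG_mRFP RGCs of cluster 2 it was 7.69%. With each cell thinned to 44732 counts, which left out 49 Hes5_GFP and 63 CAG_mRFP cells, the RGC shares were 95.96% and 71.7%. As deposited, they averaged 95.3 ± 2.54% and 73.98 ± 26.7% by day (SD, n = 3 days; two-sided exact sign-flip p = 0.25, the smallest possible). Within IPCs the fitted log2 ratio of Sox9 between groups was 0.85 ± 0.43 and within ENs -0.06 ± 1.12, each over 2 days. The difference between classes in the group ratio was tested in a separate joint fit of the classes over 2 days, so it need not equal the difference of the fits above. It was -0.12 ± 1.0 for IPCs against RGCs and -0.45 ± 1.01 for ENs against RGCs, and neither passed (adjusted p = 1 and 0.983 in edgeR with Benjamini-Hochberg adjustment). In edgeR 0 of 9903 genes differed between groups within IPCs and 0 of 10020 within ENs, with 2.80% and 3.18% at an unadjusted p under 0.05; no other tool was run there.

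Within Hes5_GFP RGCs, Sox9 was compared between the authors' cell cycle phases and stood at 631.3 CPM in G1, 581.1 CPM in S and 672.4 CPM in G2M. The log2 ratio of G1 over G2M, fitted over 3 days with at least 5 cells of each phase, was -0.34 ± 0.21 for Sox9 and -2.73 ± 0.51 for Mki67. In edgeR 0 of 10346 genes passed, Mki67 included, and 2.92% had an unadjusted p under 0.05.

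The last comparison followed Sox9 across single RGCs, within each of 5 strata of one plate batch and group with at least 20 cells. Cells are not replicates, so only mean rank correlations (Spearman rho) over strata are given, for 7055 genes with a median of 0.08. The 10 highest with one sign in all strata were Zfp36l1, an mRNA decay factor (mean rho 0.39), the condensin gene Smc4 (0.35), the mitotic kinase gene Nek6 (0.33), the Wnt effector Tcf7l2 (0.32), Alg8, Schip1, Slitrk2 and Qk, an RNA-binding protein of glia (0.31 each), Magi1 and Ttyh1 (0.30 each). The 10 lowest were Tmsb10, an actin-binding thymosin, and the ferritin gene Ftl1 (-0.31 each), Prdx2 (-0.25), Chchd2 (-0.24), the neuronal factor Neurod6 (-0.22), Abracl and Ppia (-0.21 each), Snrpg (-0.20), Cox6b1 (-0.18) and Psma7 (-0.17, with a Pearson r of the opposite sign, 0.15). Hes1 correlated at 0.30 and Pax6 at 0.23, while Hes5 was at 0.07 (-0.018 without batch L1 and 0.16 without batch 01) and Neurog2 at -0.13 (-0.25 without the CAG_mRFP stratum). In the only CAG_mRFP stratum, 28 cells of batch L1, Sox9 followed the number of detected genes with a rho of 0.85. In the Hes5_GFP strata this rho was 0.16 in batch 01, 0.28 in L1, 0.29 in L2 and 0.06 in L3, so the link was not confined to CAG_mRFP. Of the 20 genes, 8 were named again without the CAG_mRFP stratum, 6 without batch L1 and 9 without batch 01. Pax6 correlated at 0.11 without the CAG_mRFP stratum and at 0.08 without batch L1. After thinning, which removed the CAG_mRFP stratum too, 6 of the 20 genes were named again, against 8 in the same cells as deposited.

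Among lists, the 5 Notch receptors and targets had the highest median rho (0.24, percentile 100 among matched random lists), followed by Wnt (0.18, percentile 99.7), Shh (0.17, percentile 99.1), FGF and ERK (0.17, percentile 99.6), G2/M genes (0.16, percentile 100) and radial glia markers (0.15, percentile 99.7). Without the CAG_mRFP stratum the medians were 0.16 for Notch receptors and targets (percentile 99.8), 0.08 for Wnt (88.1), 0.05 for Shh (63.2), 0.12 for FGF and ERK (99.7), 0.09 for G2/M (100) and 0.06 for radial glia (89.9). Thinning left this stratum with too few cells, and the remaining 4 strata gave 0.13 (98.9), 0.09 (96.4), 0.12 (99.4), 0.12 (99.3), 0.10 (100) and 0.05 (90.8) in the same order, against 0.13 (99.3), 0.09 (95.8), 0.08 (92.6), 0.11 (99.5), 0.08 (100) and 0.04 (87.3) in the same cells as deposited. Over all 5 strata the lowest were intermediate progenitor markers (-0.09, percentile 0), Notch ligands and proneural genes (-0.09, percentile 0) and mitochondrially encoded genes (-0.06, percentile 0.02). Without the CAG_mRFP stratum these were at -0.10 (percentile 0.01), -0.08 (0.06) and -0.11 (0). S phase genes moved from 0.09 (percentile 63.7) over 5 strata to -0.01 (0.39) without the CAG_mRFP stratum and -0.05 (0) after thinning.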

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

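All tests of explanations in this part were chosen after the result was seen. Values of single days were compared with the other 3 days by Dixon's criterion in 36 sets of 4 days, of which 8 stood out, where chance gives about 1 in 20.

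Sox9 was higher in Hes5_GFP RGCs than in CAG_mRFP RGCs (log2 ratio 1.003 ± 0.28), a difference that did not pass over all genes. The log2 ratio was 0.99 ± 0.30 when cells under 44732 counts were left out and the others thinned to that depth. This kept 53 of the 72 CAG_mRFP RGCs. The ratio thus did not rest on the shallowest cells or on the larger weight of deep cells. Thinning cannot decide on depth otherwise, because it leaves the expected share of each gene in a cell unchanged, so depth stays open. Cells outside clusters 0, 1 and 3 may account for part of the difference, because within these clusters it averaged 0.71 over days and was 0.35 in summed counts (0.58 for the whole class). Within cluster 1 the difference averaged 0.37 over 2 days. Both averages included days with few CAG_mRFP cells. These values differ, so this explanation stays open. A difference between RGCs with and without Hes5 reporter activity also stays open and was not tested apart from the sort.

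Few RGCs of CAG_mRFP had an mRFP read (43.1%). Lower depth is argued against, because at equal depth the share was 18.9% (95% exact binomial interval 9.44% to 31.97%) against 82.8% of ENs (76.96% to 87.7%). Cells of low complexity are argued against too, again in pooled cells, because within clusters 0, 1 and 3 the share was 36.8% (21.8% to 54.01%). Cells without the plasmid that passed the gate stay a candidate explanation, since the share in the same clusters of Hes5_GFP was 65.5%, but a gate that picks strong reporter cells would give the same, so these cannot be told apart. No biological explanation was tested.

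Within Hes5_GFP RGCs, mRFP had a log2 ratio of 1.43 ± 0.80 between G1 and G2M. A reporter transcript that depends on phase may give this, but the test did not pass (adjusted p = 0.936, edgeR with Benjamini-Hochberg adjustment), so it stays open.

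Both reporters stood apart on day 1 in Hes5_GFP. Over all cells mRFP was at 35100.2 CPM (696.1 to 4646 on the other days), and eGFP was at 1261 CPM (92.2 to 231.7). In RGCs mRFP was at 41367 CPM (498.3 to 1933), and eGFP was at 1595 CPM (110.7 to 268.7). Day 1 also stood apart for Neurog2 in Hes5_GFP RGCs, at 81.1 CPM (0.365 to 11.4), and for Pax6 over all CAG_mRFP cells, at 240.2 CPM (73.1 to 83.7). On day 2 eGFP over all CAG_mRFP cells was at 26.3 CPM (2.08 to 4.54). On day 3 IPCs made up 12.8% of Hes5_GFP (19.2% to 20% on the other days).

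The group effect differed between ENs and RGCs for 5 of 11412 genes in an interaction test over 2 days, with edgeR and Benjamini-Hochberg adjustment. The differences in log2 ratio were -6.91 for Spc25 (adjusted p = 6.88e-04), -5.94 for Pbk, -13.36 for Fstl1, -8.16 for Ndc80 and -13.61 for Cenpe. The 45 Hes5_GFP ENs held only 2, 8, 0, 1 and 0 counts of these genes, so the fitted sizes depend on the prior count.

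Among CAG_mRFP cells, which had been sorted as GFP-negative, 12.8% had an eGFP read, and on day 2 the share was 47.8% (11 of 23).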

How the results depend on the processing

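The settings that leave out a day, omit the day block, take the plate batch as the unit, use DESeq2, leave out cluster 7, a plate or the CAG_mRFP stratum, or keep the cells of thinning as deposited, all settings for counts of genes, and other CPM minimums for single genes were chosen after the data were seen; the other settings were planned. Sox9 over all cells kept its direction in every setting, and Sox9 in RGCs kept its direction and did not pass in any (log2 ratio 0.74 to 1.20). Where a count or value changed, the cause was not tested, unless stated.

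Over all cells, Sox9 passed over all genes with DESeq2 (2.01), without a CPM minimum (2.09), at 20 CPM (2.10) and 50 CPM (2.10), with the cell filter (2.14), thinned (2.16), in per-cell mean CPM (2.24) in normalized values (1.42) and by plate batch (2.18), and leave-outs gave 1.85 to 2.38; the adjusted p ranged from 3.16e-09 to 0.423 over the settings (Benjamini-Hochberg adjustment in edgeR, limma or DESeq2). Hes5 passed with DESeq2 (2.13), in normalized values (0.33) and by plate batch (2.41). Eomes was at 0.21 with the cell filter and at -0.86 to 0.27 in leave-outs, and mRFP at -0.26 to 1.72 in leave-outs. The 42 genes were 0.399% of those tested; this became 0.171% without the day block, 11.1% with DESeq2, 0.449% without a CPM minimum, 0.908% at 20 CPM, 3.21% at 50 CPM, 1.73% thinned, 3.67% in per-cell mean CPM, 9.06% in normalized values, 2.46% by plate batch, 0.599% with the cell filter, and 0 to 2.43% in leave-outs. Of these genes, 39.8% were higher when thinned, 38.9% at 50 CPM, 69.8% in normalized values, 49.1% with DESeq2, 49.4% in per-cell mean CPM, 45.6% by plate batch and 53.3% without day 1, against 14.3% of the 42. All 42 kept their sign in every setting.

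In RGCs the count of 0 became 1.21% of tested genes with DESeq2, 0.0061% without a CPM minimum, 0.0096% thinned and 0 to 0.0095% in leave-outs; other than with DESeq2, this was 1 gene, eGFP. Genes that did not pass changed sign: Eomes was at 0.18 in per-cell mean CPM and -2.43 to 3.16 in leave-outs; Neurog2 at 0.62 without the day block, 0.018 with the cell filter, 0.30 thinned, 0.28 in per-cell mean CPM, 0.077 in normalized values and -1.12 to 0.69 in leave-outs; Tubb3 at -1.30 without the day block, -0.22 thinned, -0.19 in per-cell mean CPM, -0.20 in normalized values, -0.078 without cluster 7, -0.56 as a within-batch mean, -0.61 by plate batch and -0.96 to 1.55 in leave-outs; and Mki67 at -0.031 to 0.82 in leave-outs.

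The RGC share of Hes5_GFP was 72.9% to 80% in leave-outs. That of CAG_mRFP was 12.9% with the cell filter, 14.5% without cluster 7, 14.1% with Leiden clusters at resolution 0.6, and 14.7% to 26.8% in leave-outs. Of the 24 genes named over all cells, 12 were named again in per-cell mean CPM, 0 in normalized values and 13 to 21 in leave-outs. Of the 24 named in RGCs, 10 were named again in per-cell mean CPM, 7 with the cell filter, 0 in normalized values, 9 at 50 CPM and 7 to 9 in leave-outs. The count of 0 in normalized values may follow from their log scale, which was not tested. Of the 20 genes named by correlation, 6 were named again thinned, 8 in the same cells as deposited, 8 without the CAG_mRFP stratum, which thinning also removes, and 6 to 15 in leave-outs. Of 26 list medians, 18 to 26 kept their sign. Among 1627 values of 71 other named genes over all cells, 1303 were the same, 13.95% no longer passed, 84 newly passed, 6 moved and 7 reversed; among the values of 30 genes in RGCs, 93.5% were the same, 14 newly passed, 7 moved and 23 reversed.

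Some settings could not change a result. Another prior leaves a rank correlation as it is, the mitochondrial limit of 10% removes no cell, day 2 is not in the RGC test, and leaving out plate batch 01 or 04 gives the same test as leaving out day 1 or day 2. The RGC test without cluster 7 has only 2 days. Hes5 had a read in 46.1% of Hes5_GFP RGCs as deposited and in 43.8% after thinning, with shallower cells left out.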

Other observations

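The counts of splits were chosen after the results were seen. Exchanging the groups within days gives 8 splits of the 4 days over all cells, of which 1, the real split, gave 42 genes and the highest other gave 0. For RGCs, 4 of 4 splits gave 0 genes, the highest other also 0. Both numbers of splits are too few for a share under 0.05. Of all 35 splits of the 8 day and group sums, 3 follow the days, so that the day block could not be fitted. The highest of these counts was 0.960% of genes, for days 1 and 2 against days 3 and 4, where the real split without the day block gave 0.171%. This split follows the dates of sorting and points to a structure of the samples. Preparation dates and plates part the days in largely the same way, so these cannot be told apart. Another 24 splits, fitted with the block, gave 0 genes.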
